A study of Homo sapiens with 6 samples.

How the data were processed

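The measurement was RNA sequencing of total RNA, depleted of ribosomal RNA and prepared with a stranded kit, from libraries labelled HepG2 and transfected with siHOTAIR or siNC. The labels give 3 libraries per group, and groups were taken from the library titles. Per the submitters' processing notes the tools included HTSeq 0.6.1, DESeq and DESeq2 with the genome build hg19. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. The column names of the deposited tables are those of a DESeq2 results table, per the file headers.

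The deposited tables hold the authors' own comparison and no value per library, so 0 columns belong to single libraries. The signal in the mean column is, as deposited by the authors, the mean over libraries of counts divided by size factors. The log2 fold changes and their standard errors are the authors', as deposited, and are shrunken toward 0 for features with few reads, where no standard error exceeds 0.596. The score in the statistic column is the deposited log2 fold change divided by its standard error, and this was checked on the table. The p-values and adjusted p-values are the authors', as deposited, and recomputing a Benjamini-Hochberg adjustment over the 14597 features that have an adjusted p gave the same values within rounding. The other features with reads had lower means, up to 3.73, and no adjusted p, and 128 features are listed with a mean of 0. The call words up and down are the authors', as deposited.

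The planned edgeR test over all features, its alternatives and the estimated correlation need a count per library for every feature and were not run. The planned fallback was used: the authors' fold changes and adjusted p-values, with a threshold of 0.05. A gene rose or fell when the authors' adjusted p was under 0.05. Feature identifiers were matched to symbols with the RefSeq table of assembly GRCh38.p14, 19108 by gene ID and 386 by transcript accession, and 95 were not matched. No coordinates are printed, since that assembly differs from hg19.

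The number of libraries behind the deposited means was read from the means themselves. All 3940 features with a mean above 0 and up to 2 had a mean that is a whole-number sum of 5 steps, within 1e-10, and 0 did after a random offset. With 1 step left out, 2019 to 2389 did. Each step is what 1 read adds to the mean in 1 library. A step belongs to siHOTAIR when the features with a single read there have a fold change above 0 in the authors' deposited table, and to siNC when it lies below 0, which gave 3 and 2 libraries. The level of HOTAIR or any other gene was not used for this. The recovered size factors have a geometric mean of 1.00 with 5 libraries and 0.837 with 6. The replicate numbers of these libraries are unknown. The same steps gave a single whole-number solution for the reads of each of 10268 features with a mean above 0 and up to 100, and for HOTAIR, with the mean of 110, within 2e-12. Both procedures were tested on simulated data. Above that mean, depth per feature is known only as the mean over libraries.

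Named genes followed a rule set before the data were examined: HOTAIR, the 10 genes that rose and the 10 that fell most among those with an adjusted p under 0.05, a mean of at least 20 and a symbol, the 5 with the smallest p in each direction, and up to 4 members of a list that passed or 3 of any other. Some members that this rule names are not reported here. The rule also asked for groups that do not overlap where values per library exist. The named genes with recovered reads met this, as did 847 of all 848 called features with a mean of 20 to 100. EZH2, the abundant transcripts, the keratins, CPS1 and the plasma protein genes were singled out after their values were seen.

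The 40 gene lists were fixed before the data were examined, and 38 had at least 5 members with an adjusted p. They were tested with cameraPR (limma 3.58.1, R 4.3.3) on the deposited log2 fold changes with a preset inter-gene correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists. On permuted fold changes of the 14597 features, 83 of 120 lists shifted by 0.4 were recovered (69.2%), and 6 of 640 lists not shifted were called. Permuting removes correlation between genes, so these numbers do not give the rate of false calls for lists whose members vary together. For features with a mean of 20 to 100, limma with a mean trend was run on log2 of recovered normalized counts plus 1, and limma-voom on the recovered reads, in place of the planned count tests. In simulated counts for these 2905 features limma with a mean trend recovered 82 of 97 changes of 1 on the log2 scale and 103 of 103 of 1.5, with 5 calls among 2705 unchanged features. The simulated counts had the same preset spread between libraries for every feature, not estimated from these libraries. The numbers may therefore not hold for the real data.

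For words in 3' UTRs, the GENCODE 29 annotation gave 1 protein-coding transcript per gene. Each word of 7 bases present in at least 50 of 11016 genes was tested in a linear model of the deposited log2 fold change with the length and GC content of the 3' UTR and the GC content of the transcript, against 100 permuted sets. GC slopes used log2 of recovered reads plus 0.5, not divided by size factors. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.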

Results

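RNA sequencing compared libraries labelled HepG2, a line derived from a liver tumour, after transfection with a small interfering RNA against HOTAIR (siHOTAIR) or with a negative control (siNC). HOTAIR is a long non-coding RNA transcribed from the HOXC gene cluster, described as a scaffold for the histone-modifying complexes PRC2 and LSD1-CoREST. Total RNA depleted of ribosomal RNA was sequenced, and the labels describe 3 siHOTAIR and 3 siNC libraries. The authors' deposited table gives 1 mean normalized count, 1 log2 fold change and its p-value for each of 19589 features, with no value per library. Its means are sums of whole reads from 5 libraries, 3 on the siHOTAIR side and 2 on the siNC side, which leaves 1 labelled siNC library unaccounted for. The mean normalized counts of the authors' deposited table sum to 9.41e+06. The libraries' size factors, recovered from those means, were 1.19 and 0.893 for siNC and 1.15, 0.934 and 0.888 for siHOTAIR. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

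The first comparison asked whether HOTAIR itself was lower after siHOTAIR. HOTAIR fell to 37.9% of its siNC level, from 176 ± 36.5 normalized counts (SD, n = 2) to 66.7 ± 9.97 (SD, n = 3). The siNC libraries held 241 and 134 HOTAIR reads, and the siHOTAIR libraries 72, 73 and 53. The authors' deposited table gives HOTAIR a log2 fold change of -1.37 (SE 0.197, adjusted p = 5.6e-11). All 3 siHOTAIR libraries lay below both siNC libraries, and no further test was made on the recovered reads. The library kit keeps strand, but the strand setting of the counting is not given in the sources used here, so its count can include reads from genes on the opposite strand.

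**Figure D1:**
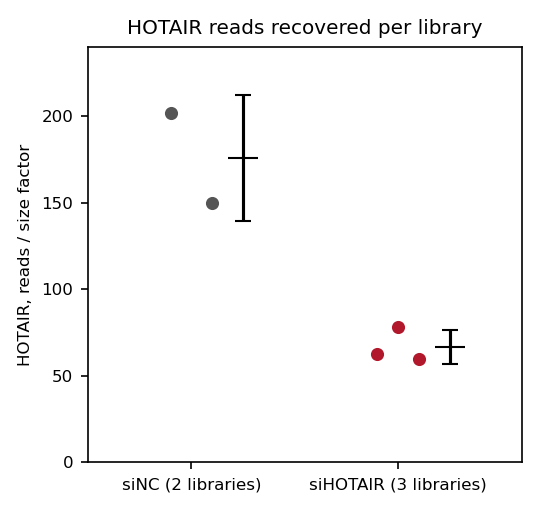
HOTAIR reads divided by the size factor (y axis) in the 2 siNC and 3 siHOTAIR libraries that make up the deposited mean; points are libraries, and the bar to the right of each group is the mean with its SD. The siHOTAIR libraries lie between 59.7 and 78.2, below the siNC libraries at 150 and 202.

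The second comparison asked which transcripts differed between siHOTAIR and siNC. Among called genes with a mean of at least 20, those that fell most in the authors' deposited table were SLFN5, a Schlafen family protein, 7.38-fold lower, FOSB, a subunit of the AP-1 transcription factor, 7.08-fold lower, and the kinase UHMK1, 6.7-fold lower. Those that rose most in the authors' deposited table were IQCN, 8.8-fold higher, the long non-coding RNA APPAT, 7.14-fold higher, and the organic anion transporter SLCO1C1, 6.57-fold higher. Over all 14597 features with an adjusted p-value in the authors' deposited table, 5900 (40.4%) had one under 0.05, of which 2925 rose and 2975 fell. A change of at least 2-fold was seen in 912 of them, 399 that rose and 513 that fell. The median size of a called change was 0.54 on the log2 scale.

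Among the 10 genes with a mean of at least 20 that fell most, the log2 fold changes in the authors' deposited table were -2.88 for SLFN5, -2.82 for FOSB, -2.74 for UHMK1 and -2.66 for BCAN (brevican, a matrix proteoglycan). They were -2.54 for CBX5 (heterochromatin protein HP1 alpha), -2.52 for MICOS10 (a part of the mitochondrial cristae complex), -2.49 for TCEAL4 and -2.46 for SMIM14 in the authors' deposited table. ZKSCAN3, a zinc finger protein, had -2.43 and STEAP4, a metalloreductase, -2.36 in the authors' deposited table. The standard errors in the authors' deposited table ranged from 0.0806 for STEAP4 to 0.417 for SMIM14, the member with the lowest mean. SLFN5 was at 181 and 146 normalized counts in the siNC libraries and at 24.3, 23.6 and 11.3 in the siHOTAIR libraries.

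Among the 10 genes with a mean of at least 20 that rose most, the authors' deposited table gives log2 fold changes of 3.14 for IQCN, 2.84 for APPAT, 2.72 for SLCO1C1 and 2.66 for the interleukin 12 receptor subunit IL12RB2. It gives 2.51 for NPR3 (the clearance receptor of natriuretic peptides), 2.48 for OVGP1 (oviductal glycoprotein), 2.42 for OTOF (otoferlin), 2.28 for ALPK3, and 2.27 for both NKAIN4 and TNXB (tenascin XB). Standard errors in the authors' deposited table ran from 0.222 for NPR3 to 0.47 for OVGP1. IL12RB2 was at 10.1 normalized counts in both siNC libraries and at 76.2, 67.4 and 86.7 in the siHOTAIR libraries. OVGP1 rested on fewer reads, with 0.84 and 6.72 normalized counts in siNC against 32, 23.6 and 37.2 in siHOTAIR.

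The smallest p-values belonged to more abundant transcripts. In the authors' deposited table CBX5 fell by 2.54 on the log2 scale (SE 0.0835, adjusted p = 3.1e-199), STEAP4 had -2.36 (adjusted p = 3.4e-185) and UHMK1 -2.74 (adjusted p = 5.51e-140). The organic anion exporter ABCC3 had -2.27 (adjusted p = 7.68e-129) and FOS, a further AP-1 subunit, -1.52 (adjusted p = 4.35e-104) in the authors' deposited table. In the other direction the authors' deposited table gives SCARA3 2.05 (adjusted p = 2.26e-159), the opioid growth factor receptor OGFR 2.09 (adjusted p = 8.13e-148) and GALNT2, an enzyme that starts O-glycosylation, 1.52 (adjusted p = 4.35e-107). TSC22D1 had 1.69 (adjusted p = 2.74e-94) and the endocytic adaptor EPN1 1.52 (adjusted p = 9.49e-87) in the authors' deposited table. CBX5, STEAP4, UHMK1 and ABCC3 each carry AGAGAGA or AAGAGAG in their 3' UTR, words whose carriers had lower fold changes than other genes; EPN1, which rose, carries both, and FOS, which fell, carries neither. The 3' UTRs of CBX5, STEAP4 and UHMK1 are 7060 to 10815 bases long. One of these words is carried by 40.2% of the 371 searched genes that fell at least 2-fold and by 23.4% of the others. The words were picked from these same fold changes.

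**Figure D2:**
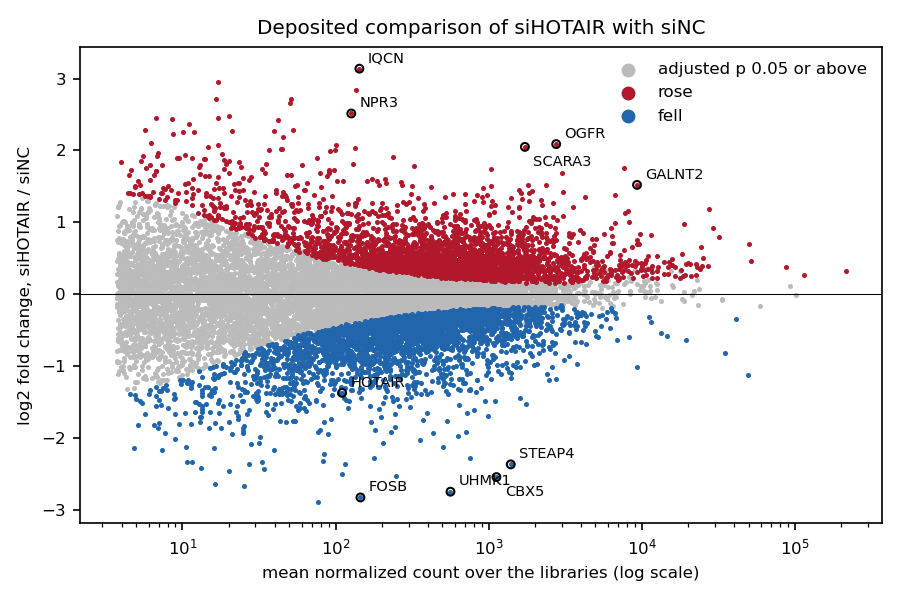
Log2 fold change of siHOTAIR over siNC (y axis) against the mean normalized count on a log scale (x axis) in the authors' deposited table, for the 14597 features with an adjusted p. Points in red rose and points in blue fell at an adjusted p under 0.05, grey points did not pass, and circles mark HOTAIR and named genes.

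The 3 siHOTAIR libraries resembled one another. Among 2905 features with a mean of 20 to 100, for which the reads of each library were recovered, the Pearson correlation of log2 normalized counts across genes, which are not independent replicates, was 0.869 to 0.896 within siHOTAIR. It was 0.912 between the siNC libraries and 0.53 to 0.609 between the groups. A narrow range of means lowers such correlations, so these values do not describe all features.

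The authors' own list of differential genes holds 766 features, 321 called up and 445 called down in the authors' deposited table. Each of the 673 with an adjusted p had one below 0.001 and a change of at least 2-fold. The other 93 have no adjusted p in the authors' deposited table, with 53 called up and 40 called down. These 93 are all the features with a change of at least 2-fold and no adjusted p, so a missing adjusted p did not stop a call. They had 7 to 19 reads over the 5 libraries, and 51 had an unadjusted p of 0.05 or above in the authors' deposited table. At this depth their calls rest on few reads and on no adjusted p limit.

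The third comparison asked whether groups of genes fixed before the data were examined moved together. Ribosomal protein genes, which encode the structural proteins of the ribosome, stood out: 28 of 36 rose, 0 fell and 8 did not pass, by the adjusted p of the authors' deposited table. Their median log2 fold change was 0.35, and RPS2 (0.51), RPS6 (0.49), RPS12 (0.49) and RPL11 (0.43) had the smallest p-values in the authors' deposited table. This was the only one of 38 lists past the list test (cameraPR, limma, preset correlation 0.01, two-sided, adjusted p = 0.0393), a test across genes and not across replicates. With a preset correlation of 0.05 its adjusted p was 0.345, and an estimated correlation could not be had, as 0 of its members had recovered reads. Reads of ribosomal protein genes can be shared with their many pseudogenes, so single members are uncertain.

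The protein partners described for HOTAIR moved in both directions. Of 16 PRC2 and LSD1-CoREST genes, 4 rose and 2 fell (list adjusted p = 0.916). KDM1A, the histone demethylase LSD1, fell and was 2.01-fold lower (adjusted p = 8.57e-46), while PHF19 (0.68) and JARID2 (0.53), accessory subunits of PRC2, rose in the authors' deposited table. The catalytic subunit EZH2 had 0.10 (SE 0.101, adjusted p = 0.45) in the authors' deposited table. In the HOXD cluster, the site at which HOTAIR was first described to act, 0 of 7 genes rose and 2 fell (list adjusted p = 0.232). These were HOXD11 (-1.51, mean 5.45) and the neighbouring MTX2 (-0.32), and HOXD10 had -1.11 with an adjusted p of 0.11 in the authors' deposited table. In the HOXC cluster 3 of 12 rose and 0 fell (list adjusted p = 0.659), namely HOXC10 (0.45), HOXC13-AS (0.82) and HOXC11 (0.36) in the authors' deposited table.

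Several stress and signalling groups had more members that fell than rose, without passing the list test. Of 19 hypoxia targets 13 fell and 1 rose (median -0.32, list adjusted p = 0.0983): the collagen cross-linking enzyme LOX (-1.36) and NDRG1 (-0.69) fell and ERO1A (0.86) rose in the authors' deposited table. Of 20 NRF2 targets, which include antioxidant and detoxification genes, 10 fell and 4 rose (list adjusted p = 0.0983). ABCC3 (-2.27), TXNRD1 (-0.86) and AKR1C3 (-1.42) had the smallest p-values in the authors' deposited table. AKR1C3 shares sequence with its AKR1C neighbours. Replication-dependent histone genes had the lowest median of all tested lists, -0.42, with 6 of 21 that fell and 1 that rose (list adjusted p = 0.0501). Of these H2BC21 (-1.12) and H2AC6 (-1.31) fell and H2BC5 (0.73) rose in the authors' deposited table; histone genes share sequence and their reads may be split. Among 14 immediate early genes 6 fell and 3 rose (list adjusted p = 0.172), with FOS (-1.52) and FOSB (-2.82) down and MYC (0.57) up in the authors' deposited table. Among 13 genes of the NF-kB and cytokine response 4 fell and 1 rose (list adjusted p = 0.367), including NFKBIA (-0.49), NFKB1 (-0.74) and NFKB2 (-0.40) in the authors' deposited table.

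TGF-beta targets leaned upward, with 9 of 18 that rose and 4 that fell (median 0.43, list adjusted p = 0.172). The inhibitors of differentiation ID3 (1.31) and ID1 (1.01) rose, while TGFBI (-1.22) fell in the authors' deposited table. Of 30 interferon-stimulated genes 6 rose and 7 fell (list adjusted p = 0.659): IFIT1 (1.30), OASL (0.97) and BST2 (0.64) rose in the authors' deposited table. Of 24 p53 targets 8 fell and 3 rose (list adjusted p = 0.62), and the cell cycle inhibitor CDKN1A (-0.92), ZMAT3 (-0.98) and GDF15 (-1.33) led those that fell in the authors' deposited table. Apoptosis regulators were divided, with 5 of 20 that rose and 6 that fell (list adjusted p = 0.659), among them BCL2L1 (0.83) and BIRC3 (-0.83) in the authors' deposited table. Of 11 Wnt targets 3 rose and 2 fell (list adjusted p = 0.983), with GLUL (-1.34), MYC (0.57) and TBX3 (0.60) in the authors' deposited table.

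In the cell cycle lists, 9 of 30 genes of G1/S and DNA replication rose and 4 fell (list adjusted p = 0.4), with CDT1 (0.96), GINS2 (1.08) and E2F1 (0.84) up in the authors' deposited table. Of 29 G2/M and mitosis genes 6 rose and 2 fell (list adjusted p = 0.709): ANLN (-0.84) fell, and BIRC5 (0.56) and TOP2A (0.39) rose in the authors' deposited table.

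None of the metabolic lists passed the list test. Of 22 glycolysis genes 11 fell and 2 rose (list adjusted p = 0.4), where PFKL (0.76) rose and HK2 (-0.88) and PFKM (-0.56) fell in the authors' deposited table. Of 10 genes of gluconeogenesis and glycogen 3 fell and 0 rose (list adjusted p = 0.62), namely GBE1 (-0.73), PYGL (-0.57) and PGM1 (-0.36) in the authors' deposited table. Of 25 cholesterol synthesis genes 10 rose and 6 fell (list adjusted p = 0.651), with DHCR7 (0.49) up in the authors' deposited table. In fatty acid and triglyceride synthesis 5 of 20 rose and 5 fell (list adjusted p = 0.659), including FADS1 (-0.99), ELOVL1 (0.80) and ME1 (1.03) in the authors' deposited table. In fatty acid oxidation 4 of 21 rose and 7 fell (list adjusted p = 0.62), including PDK4 (1.79), ETFB (-1.17) and ECI1 (0.91) in the authors' deposited table. Of 29 genes of oxidative phosphorylation 9 fell and 2 rose (list adjusted p = 0.651), with NDUFS1 (-0.73), SDHC (-0.59) and NDUFB5 (-0.57) down in the authors' deposited table. Of 9 genes of bile acid and drug metabolism 2 rose and 0 fell (list adjusted p = 0.172), the sterol hydroxylase CYP27A1 (2.71, mean 16.5) and SLC27A5 (0.61) in the authors' deposited table. CYP1B1, the next by p-value, had 0.98 with an adjusted p of 0.072 in the authors' deposited table.

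In the proteostasis and amino acid lists, 5 of 21 ATF4 and amino acid response genes rose and 6 fell (list adjusted p = 0.659). The amino acid transporter subunits SLC3A2 (1.01) and SLC7A5 (0.92), and DDIT4 (0.76), rose in the authors' deposited table. Of 19 genes of the unfolded protein response 4 rose and 3 fell (list adjusted p = 0.953), with XBP1 (-0.87), SEL1L (-1.01) and HYOU1 (-0.48) leading in the authors' deposited table. Of 13 heat shock genes 3 rose and 6 fell (list adjusted p = 0.709): HSP90AA1 (0.83) and HSPD1 (0.46) rose and HSPA1B (-0.60), a near copy of HSPA1A, fell in the authors' deposited table. Of 7 metallothionein and iron genes 3 rose and 1 fell (list adjusted p = 0.651), with MT2A (0.54), IREB2 (-0.65) and MT1E (0.88) in the authors' deposited table. Of 5 acute phase genes 1 rose and 2 fell (list adjusted p = 0.63): CFB (-0.98) and C3 (-0.49) fell and SOCS3 (0.37) rose in the authors' deposited table.

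Lists of adhesion, motility and non-coding RNA genes did not pass the list test. Of 18 epithelial adhesion genes 1 rose and 4 fell (list adjusted p = 0.659), led by DSP (-0.79), JUP (-0.64) and TJP3 (-0.50) in the authors' deposited table. Of 19 mesenchymal and motility genes 3 rose and 3 fell (list adjusted p = 0.651): fibronectin FN1 (-0.67) and ITGB1 (-0.58) fell and SNAI2 (1.16) rose in the authors' deposited table. Of 15 long non-coding RNAs other than HOTAIR 6 rose and 1 fell (list adjusted p = 0.62), with GAS5 (1.08) and SNHG1 (0.85), hosts of small nucleolar RNAs, up and TUG1 (-0.65) down in the authors' deposited table. Of 13 genes of the RNAi and microRNA machinery 1 rose and 3 fell (list adjusted p = 0.62), and those that fell were DICER1 (-0.70), DROSHA (-0.46) and PRKRA (-0.73) in the authors' deposited table. Of 9 small structural RNAs 0 rose and 3 fell (list adjusted p = 0.62): the signal recognition particle RNAs RN7SL1 (-0.81) and RN7SL2 (-1.13), near copies of each other, and RMRP (-0.61) in the authors' deposited table.

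Markers of other cell types were included to see whether they moved with the groups. Of 10 fibroblast and stellate markers 4 rose and 0 fell (median 0.32, list adjusted p = 0.172), with the collagen genes COL5A1 (1.13) and COL1A1 (0.86) and PDGFRB (1.24) leading in the authors' deposited table. Of 6 endothelial markers 2 rose and 0 fell (list adjusted p = 0.172), ENG (0.54) and VWF (1.85, mean 5.38) in the authors' deposited table. CDH5 had 0.47 with an adjusted p of 0.067 in the authors' deposited table. Of 6 leukocyte markers 0 rose and 1 fell (list adjusted p = 0.62), CD68 (-0.47) in the authors' deposited table. Of 7 markers of keratinocytes and other epithelial lines 0 rose and 3 fell (list adjusted p = 0.62), KRT17 (-0.31), NKX2-1 (-0.59) and PAX8 (-0.75) in the authors' deposited table. Of 10 hepatocyte transcription factors 0 rose and 2 fell (list adjusted p = 0.709), PPARA (-0.99) and GATA6 (-0.54), and CEBPA had 0.31 with an adjusted p of 0.052 in the authors' deposited table.

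Adjustment over the list alone left the counts of 29 lists as they were and changed 10. Adjusted over the list alone, 31 ribosomal protein genes rose and 0 fell, 11 and 6 genes of cholesterol synthesis, 6 and 5 of fatty acid synthesis, and 5 and 7 of fatty acid oxidation. Adjusted over the list alone, 5 genes of G2/M and mitosis rose and 2 fell, 5 and 8 p53 targets, 4 and 6 heat shock genes, and 3 and 7 immediate early genes. The counts adjusted over the list alone were 3 and 9 for oxidative phosphorylation and 1 and 5 for histones. In 6 lists the median, the mean and the test differed in sign, namely bile acid and drug metabolism, p53 targets, the unfolded protein response, the ATF4 response, Wnt targets and epithelial adhesion.

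**Figure D3:**
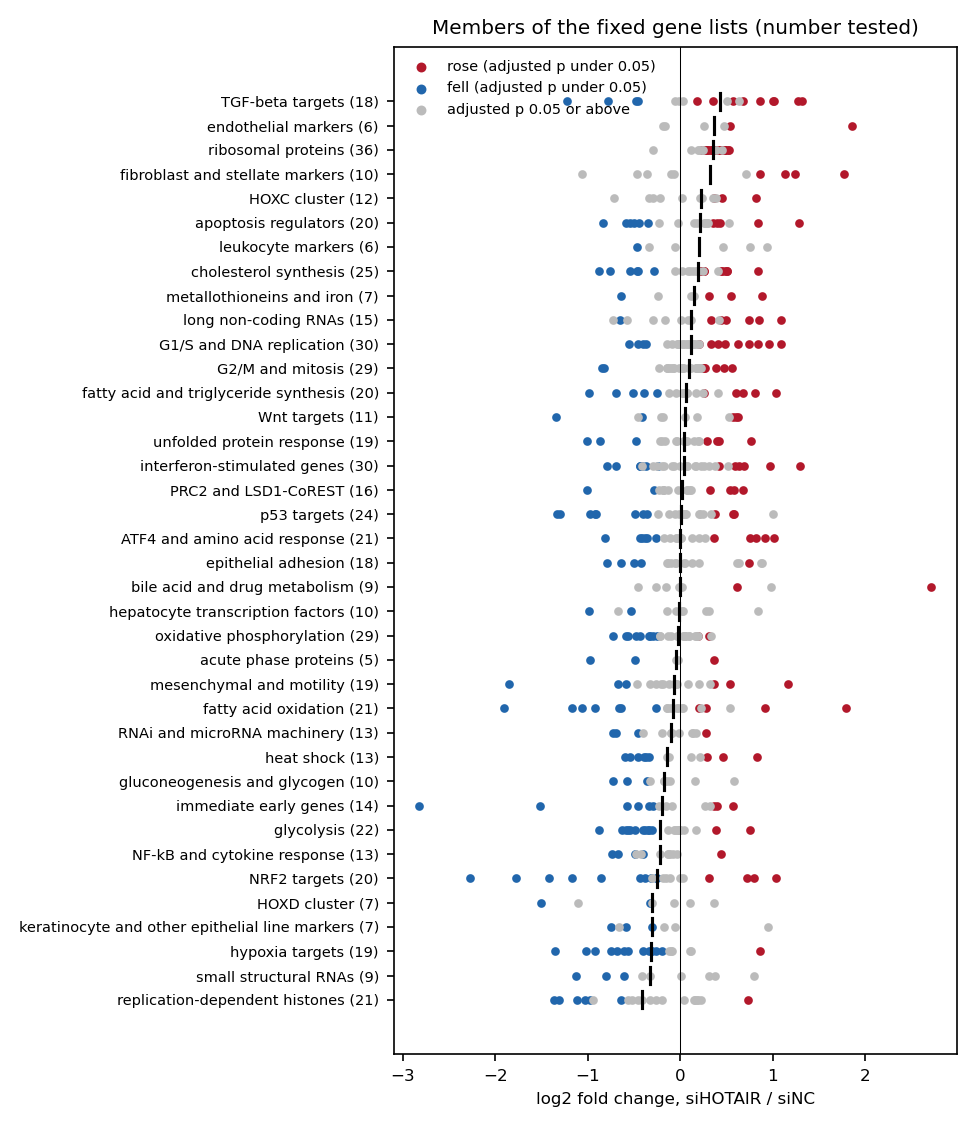
Log2 fold change of siHOTAIR over siNC (x axis) in the authors' deposited table for the tested members of 38 gene lists (y axis, number tested in brackets). Each point is a gene, red if it rose, blue if it fell and grey if its adjusted p was 0.05 or above, and black bars are list medians, with ribosomal proteins at 0.35 and histones at -0.42.

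Transcripts of hepatocyte plasma proteins were low in libraries of both groups. Of 32 genes for plasma proteins made by hepatocytes, 20 were in the authors' deposited table, with a median mean normalized count of 0.62 against 78.7 over all features. VTN was the highest of these at 64.7 in the authors' deposited table, and APOA1 (0.382) and SERPINA1 (0.167), which encode abundant plasma proteins, rested on 2 reads and 1 read. In the 2 siNC libraries, 19 of the 20 genes had 20 or fewer reads. Only 4 of them had an adjusted p in the authors' deposited table, too few for the list test: F10 rose (1.65, mean 4.5), and F2 had 0.75, VTN -0.29 and PLG 0.38 without passing. In contrast CPS1, a urea cycle enzyme that hepatocytes express, had a mean of 23334 in the authors' deposited table, and the keratin genes KRT8 and KRT7 had means of 22106 and 11514. ALB and AFP were not analysed here, and the list of mitochondrially encoded genes had 0 members in the table.

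**Figure D4:**
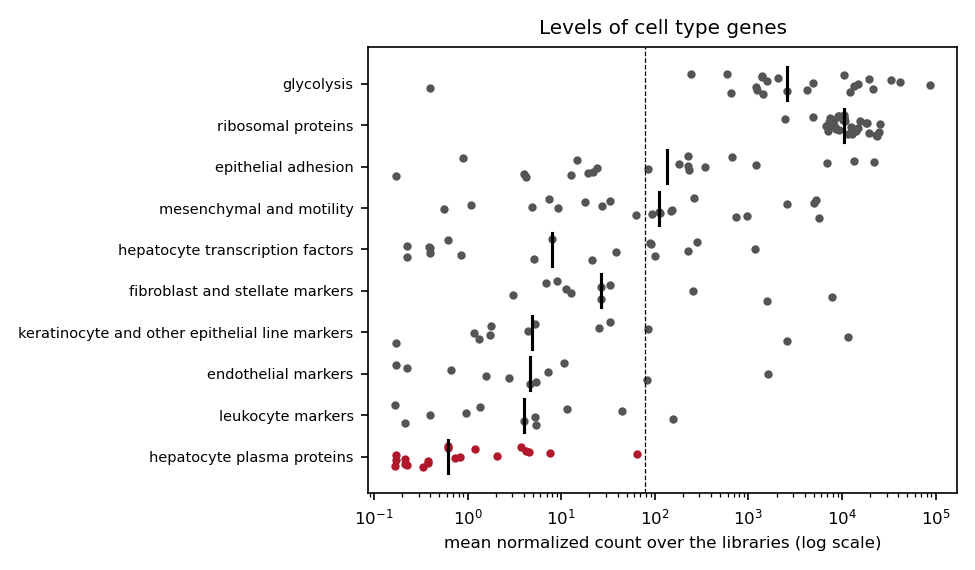
Mean normalized count over the libraries in the authors' deposited table (x axis, log scale) for members of 10 gene lists (y axis). Each point is a gene, black bars are list medians and the dashed line is the median of all listed features, 78.7; hepatocyte plasma proteins (red) have a median of 0.62.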

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

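The limma and voom fits on recovered reads, the library left out, the filter on the mean, the added list settings and the removal of calls without an adjusted p were chosen after the data were seen. The planned tests with edgeR, DESeq2, limma-voom and fry, the other normalizations, the filter on CPM, the replicate left out by number, the change of pseudocount and the estimated correlation were not run over all features, because they need values per library. Of these only limma-voom was also run on the features with a mean of 20 to 100. No paired analysis was possible because the deposited comparison carries no replicate numbers. The count of 5900 changed genes was 912 when a change of at least 2-fold was also asked for, which admits fewer genes by construction, and lay between 4511 and 5837 at an adjusted p under 0.01, with no filter, or with a mean of at least 20. Against the authors' 766 calls, an adjusted p under 0.05 gave 5900 and an unadjusted p under 0.05 gave 6876, both with the fold criterion dropped and the p threshold relaxed. With the fold criterion kept these thresholds gave 912 and 1038, and 673 calls have an adjusted p. HOTAIR's log2 fold change was -1.40 without shrinkage. For the 1 list called, ribosomal proteins, the adjusted p ranged from 3.57e-05 to 0.345 over the settings. The Wald statistic in place of the fold change called 7 lists: ribosomal proteins, fibroblast markers (0.0265) and TGF-beta targets (0.0495) upward, and hypoxia (0.00221), NRF2 (0.0236), glycolysis (0.0236) and immediate early genes (0.0236) downward. With the trend along GC content and length removed 2 lists were called, with histones (0.0241) added. Among 11716 genes not known to carry the 4 words AGAGAGA, AAGAGAG, TCGGAGA and CGGAGAA in their 3' UTR, 3 lists were called, with histones and TGF-beta targets (both 0.0466) added. The words were searched for and not found in 8135 of these genes. The rest were not searched, such as those with a mean under 20, and may carry them. With a correlation of 0.05, cameraPR called 0 lists, with 4 at an unadjusted p under 0.05. The cause of these changes was not tested. Among features with a mean of 20 to 100, limma on recovered reads called 1145 against 848 in the authors' deposited table, including all 848, and limma-voom called 1160, including all 848. Leaving out 1 library in turn gave 751 to 1068 calls with limma. The lowest count came without siNC library 2, and 1145 is 1.52 times as high. Of the authors' 848 calls, 672 were shared without siNC library 2, 688 without siNC library 1 and 816 to 830 without a siHOTAIR library; where a siNC library is left out, the lone other one is assumed to vary like the siHOTAIR libraries. The 11 named genes with recovered reads passed with each siHOTAIR library left out. They were chosen as the most changed in these same libraries, so passing was likely beforehand. Their direction held in all 55 values with a library left out, but their size could move. OVGP1 had a log2 fold change of 3.06 with limma on all libraries, 2.02 without siNC library 1 and 4.10 without siNC library 2. For named genes the other settings move an adjusted p too little to end a call. Depth limits the features with a mean under 3.73, which have no adjusted p.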

Other observations

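The groups of transcripts in the next paragraph were chosen after their values were seen. So were the tests of base composition, of both kinds of seed sites, of hepatocyte transcripts and of GC content without 11 words. The tests of the coding sequence, of GC content without 4 words and of GC slopes between libraries were set down before their results were seen.

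Small nucleolar RNA and microRNA genes had medians above 0, without a test of either class. Of 137 small nucleolar RNAs with an adjusted p in the authors' deposited table, 10 rose and 1 fell, with a median log2 fold change of 0.27. Of 102 microRNA genes 6 rose and 1 fell, with a median of 0.28 in the authors' deposited table. Over all 14597 features with an adjusted p 40.4% were called, so a smaller share of both classes was called. Whether their reads came from longer host transcripts was not tested. Of 1063 long non-coding RNAs 102 rose and 104 fell in the authors' deposited table. Among the most abundant transcripts, MALAT1 took 2.29% of all mean normalized counts and H19 0.993%. The cytoskeletal linker PLEC (1.19, SE 0.0981), the elongation factor EEF2 (0.70) and the ferritin light chain FTL (0.79) rose in the authors' deposited table, while H19 had 0.12 with an adjusted p of 0.293. Others of the most abundant transcripts, RN7SL2 (-1.13), RN7SL1 (-0.81) and ENO1 (-0.35), fell in the authors' deposited table.

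Words of 7 bases in 3' UTRs separated lower from higher genes: over 16158 words, carriers of AGAGAGA had a fold change that differed by -0.18 on the log2 scale (SE 0.0135, z = -13.5) and carriers of TCGGAGA one that differed by 0.21 (z = 6.31), outside the range of -5.17 to 5.03 in permuted sets. The test of an equal effect of AGAGAGA anywhere in the mRNA cannot decide. The word was picked by its value in the 3' UTR, which favours a larger difference there. The 2 standard errors were combined as if independent, though both fits used fold changes of largely the same genes. The AGAGAGA difference in the 3' UTR minus that in the coding sequence was -4.39 combined standard errors. Carriers in the coding sequence also differed, by -0.10 (SE 0.0124, 2356 genes). The test of base composition or length cannot decide either. In it AAGAGAG, the weaker of the pair AGAGAGA and AAGAGAG, lay -4.89 z units from the lowest of 33 other words of the same bases. The pair was picked as the 2 lowest words, so a place below the others was fixed beforehand. The lowest of these others, GAGAGAA (z = -6.65), was itself outside the permuted range. Seed sites of the siRNA against HOTAIR remain open for the low words. HOTAIR holds 6 of the 10 lowest words, but 10.3% of transcripts of similar length hold at least as many. The siRNA sequences are not given in the sources used here, so 3 HOTAIR duplexes known from general use were tried. For each strand 1 site was scored. In 1 duplex the antisense and sense sites (CAGAGAG and TCCCGTT) had ranks 3 and 33 from the lowest. That duplex itself ends in AGAGAGA, the lowest word. This word pairs with its antisense strand 1 base away from CAGAGAG, and was not scored as a site. The other duplexes had their sites at ranks 427 to 10993. For the high word, seed sites of a commonly sold negative control siRNA are a candidate explanation, although the use of that duplex is an assumption. The sites of its strands, TCGGAGA and TGTCACG, ranked 1 and 3 from the highest among all words. Of these TGTCACG (z = 4.48) lay inside the permuted range. CGGAGAA, which overlaps TCGGAGA and pairs with the same strand 1 base away, was not scored as a site. It ranked 2 from the highest (z = 5.46), outside the permuted range. An effect of HOTAIR loss itself was not tested apart from these words.

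The low plasma protein transcripts stand apart from the label HepG2, a line known to secrete many plasma proteins. A loss after HOTAIR knockdown is argued against by a median of 1.5 reads per gene in the siNC libraries. Cultures that were not HepG2-like hepatoma cells are a possible explanation, with the 20 listed plasma protein genes at a median percentile of 12.2 among all features and 0 of them above the 90th percentile. CPS1, a urea cycle enzyme of hepatocytes, goes the other way, with a mean normalized count of 23334 in the authors' deposited table. The 17 of 21 listed hepatocyte transcription factors with a row had a median of 7.92 (percentile 31.4, with HNF4A at 5.06 and CEBPB the highest). KRT7, a keratin listed for other epithelial lines, had 11514 but was the highest of its list. The median of that list was 4.85 (percentile 27.45, 12 genes with a row), no higher than that of the hepatocyte transcription factors. Features without a row (12 of the 32 listed plasma protein genes) or lost in the authors' counting stay open, since KIF2C, a mitosis gene, had a mean of 0.428 in the authors' deposited table and was the only 1 of 30 listed G2/M genes under 1, against 13 of 20 plasma protein genes, and no other cell line was tested as a source.

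The fold change rose with the GC content of the transcript (Spearman's rho = 0.235 across 12782 genes, which are not independent replicates): 39.7% of 1279 genes with a GC content of at least 62.9% rose and 8.44% fell, against 13.2% and 25.1% of 1279 genes with at most 39%. Sites of AGAGAGA, AAGAGAG, TCGGAGA and CGGAGAA in 3' UTRs are argued against as its cause, since among the 11016 genes searched for words rho was 0.241, and the 8135 without these 4 words had one 0.993 times as high. Without all 11 words outside the permuted range it was 1.03 times as high (5402 genes), but other seed sites stay open, as the siRNA sequences are not given in the sources used here. GC bias that varies between libraries cannot be told apart from an effect of the transfection: the slope between the groups was 0.178 per 10% of GC (SE 0.0155), and the largest slope between libraries of 1 group was 0.62 times as large. With the trends along GC content and transcript length both removed, over the 12782 genes, ribosomal proteins stayed past the list test (adjusted p = 0.00192). Removal of the GC trend alone was not tested.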
